A study of Homo sapiens with 4 samples.

How the data were processed

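Total RNA of NB4 cells, an established acute promyelocytic leukaemia line, was measured on 4 Affymetrix human exon arrays, with 1 array each for untreated cells and for cells after 48, 72 and 96 h of all-trans retinoic acid. The groups and times were taken from the labels, and all 4 arrays had a group. Per the labels' protocols, RNA was extracted with RNAbee and labelled with biotin using the Affymetrix whole-transcript terminal labeling kit. The deposited values are gene-level intensities on a linear scale for 22011 core transcript clusters, as the values themselves show. Per the submitters' processing notes they were made with Affymetrix Expression Console, without a version, and per the labels the probe group and core meta-probeset files were those of build hg18. The background correction, the summarisation of probes and the normalization between arrays are not given in the sources used here, and the medians of the 4 arrays differed.

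The plan written before the data were examined took log2 of the values directly. Because the linear intensities reached down almost to 0, values under 16 were set to 16 before log2, and this floor was chosen after the values were seen. Clusters were named through the platform annotation. Of the clusters, 14432 had exactly 1 gene symbol, 2408 had several and 5171 had none, and only the first kind was used. Of the 14432, 14404 matched the reference gene table of assembly GRCh38.p14 by Entrez identifier and 28 did not, and 0 symbols changed. That table served for names and genomic span, and no coordinates are given because its build differs from that of the arrays. The log2 values of the 197 genes with several clusters were averaged, which gave 14232 genes. Genes were tested where the highest of their 4 log2 values reached the median of the whole table (50th percentile, 7.11 on the log2 scale, an intensity of 138), which left 8910 genes. Of these, 144 lay at the floor on an array.

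A gene was counted as higher or lower where its log2 difference was at least 1. With 1 array per group no test between groups was possible, so a rule of size replaced it. A fold against an array at the floor is given as a lower bound. For 27 gene lists holding 583 genes, fixed before the data were examined, the median log2 difference of the measured members was set against 10000 random lists of the same size drawn from 20 bins of mean level, and a list was called shifted at or beyond the 2.5th or 97.5th percentile. Lists with under 5 measured members received no percentile. The percentile describes these arrays and is not a test between conditions. Counts that noise gives were estimated from 100 sets of simulated unchanged arrays, with noise drawn from the centred differences between the 96 and 72 h arrays, which hold true change as well as noise, so the simulated counts lean high.

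Named genes were chosen by a rule fixed before the data were examined. It took the 12 genes higher and the 12 lower at all 3 times with the largest smallest difference, the 3 members of each list with the largest mean difference and another that went the other way by at least 1, and 14 genes named in advance, of which 12 were measured. It also took the 5 largest rises and the 5 largest falls from 48 to 96 h with an intermediate 72 h value, and the 5 genes with the largest sum of opposite differences. Genes at the floor were not ranked among the 12 or among the rises and falls, a limit that was not part of the rule as first fixed. Exceptions are said to have been named after their values were seen.

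Alternatives fixed in advance were quantile normalization, centring each array on its median, a pseudocount of 16, no level filter, a filter at the 70th percentile, size rules of 1.5-fold and 3-fold, leaving out each time, the mean in place of the median, and the cluster with the highest mean for each gene. No floor, a floor of 64 and centring on the reference genes were added after the data were seen. Alternatives used 2000 random lists. The steps were tested on simulated data with changes planted among 8910 genes. At 96 h against untreated, 47.8% of genes changed 2-fold, 98.5% of those changed 4-fold and 100% of those changed 8-fold were found, and 6.73% of unchanged genes were called. Of 100 lists of unchanged genes, 7 fell outside the central 95% of random lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.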

Results

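NB4 is an established human cell line from acute promyelocytic leukaemia that carries the PML-RARA fusion, and all-trans retinoic acid (ATRA) is the ligand that drives such cells toward granulocytes. Gene-level intensities were measured on 4 exon arrays, from untreated cells and from cells after 48, 72 and 96 h of ATRA, to follow expression over the course of treatment. Each time was represented by 1 array, so no difference reported here has a replicate check and no p-value is given. A gene is called higher or lower where it differed at least 2-fold, and a gene list is called shifted where its median lay outside the central 95% of 10000 random lists matched on level. The median intensity over the 22011 transcript clusters was 136.4 in untreated cells and 138.4, 130.6 and 146.6 at 48, 72 and 96 h. Between 10.7% and 12.6% of clusters per array lay at or under a floor of 16, and 8910 genes passed the filter on level. The number of arrays limits the precision of every value.

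Among genes with no value at the floor, ALOX5AP, CCL2, S100A8, DHRS3, ICAM1 and ASB2 were among the 12 with the largest rises held at all 3 times. Genes left out for a floor value can exceed some of these, such as CYP26A1, which was at least 6.57 above untreated on the log2 scale at each time. ALOX5AP, which encodes the activating protein of 5-lipoxygenase, was 309-fold higher at 48 h than in untreated cells and 333-fold higher at 72 h. The chemokine CCL2 was 119-fold, the calgranulin S100A8 149-fold and the retinaldehyde reductase DHRS3 95.8-fold higher at 48, 72 and 72 h respectively. ICAM1, an adhesion molecule, was 85.9-fold higher at 48 h, and ASB2, a retinoic acid target that specifies a ubiquitin ligase, was 53.2-fold higher. The remaining leaders were the potassium channel KCNH4, the transglutaminase TGM2, the adhesion receptor ADGRG3, PLAAT4, the costimulatory receptor TNFRSF9 and complement C3, with log2 differences at 96 h of 5.73, 5.72, 5.61, 6.10, 5.97 and 5.94. Of these 12 genes, ALOX5AP, S100A8, DHRS3, ASB2, KCNH4, ADGRG3, PLAAT4 and TNFRSF9 had untreated intensities from 17.25 to 36.1. These lie under the lower quartile of the untreated array (39.4), so the sizes of their folds are uncertain.

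Among genes with no value at the floor, those with the largest falls held at all 3 times included the protease inhibitor CST7 (cystatin F). CST7 was 19.5-fold, 50.3-fold and 32.2-fold lower at 48, 72 and 96 h. CTSG, left out of the ranking because it lay at the floor at 72 and 96 h, fell further, by 36.3-fold at 48 h. NOG, which encodes the BMP antagonist noggin, was 25.1-fold lower at 48 h, and the transcriptional repressor BCL11A was 14.7-fold lower. SPNS3, MTSS2, MTARC1, the calpain CAPN2 and the potassium channel KCNH2 differed by -3.89, -3.83, -3.65, -3.47 and -3.63 on the log2 scale at 48 h. OAF, the growth factor binding protein IGFBP4, NT5DC2 and the fatty acid elongase ELOVL3 differed by -3.74, -3.24, -3.29 and -3.26. In all, 711 genes were higher and 887 lower than untreated at all 3 times. Unchanged arrays simulated against the same untreated array gave at most 68 and 53 such genes. Of the 711 genes 73, and of the 887 genes 38, had a value at the floor on an array, so their sizes are bounds.

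Genes of retinoid metabolism and retinoic acid targets rose together. Of 17 measured members of this list, 14 were higher and 2 lower at each of the 3 times, and the list median was 14.2-fold, 16.7-fold and 14.8-fold above untreated at 48, 72 and 96 h, against a random range of -0.62 to 0.38 on the log2 scale at 48 h. CYP26A1, the enzyme that degrades retinoic acid, stood at the floor in untreated cells and was at least 95.2-fold higher at 72 h. TGM2 was 100.8-fold higher at 48 h and 52.7-fold higher at 96 h. RDH10, which makes retinaldehyde from retinol, went the other way, with log2 differences of -2.32, -3.66 and -2.59. The other lower member was the retinoid receptor RXRA, at -2.89, -2.67 and -2.43, which was named after its values were seen. The 2 partners of the fusion had log2 differences of -0.79, -1.0 and -0.71 (PML) and -0.64, -0.98 and -0.90 (RARA) at 48, 72 and 96 h, and gene-level values do not separate the fusion from the normal transcripts.

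Surface receptors, integrins and calgranulins of maturing granulocytes were higher from 48 h and rose further by 72 h, while the step from 72 to 96 h (0.23) lay inside the random range and turned to -0.091 with reference centring. The list median was 3.29-fold, 6.22-fold and 7.93-fold above untreated at 48, 72 and 96 h, and 13, 15 and 16 of 17 measured members were higher, with none lower. ITGAX, an integrin subunit of mature myeloid cells, was 16.5-fold higher at 48 h and 56.6-fold higher at 96 h. S100A8 and ICAM1, members of the same list, stood at 7.32 and 6.38 on the log2 scale above untreated at 96 h. The NADPH oxidase list, the enzyme complex of the oxidative burst, was also shifted upward, with medians of 1.21, 1.08 and 1.17 over 5 measured members. CYBB, its catalytic subunit, was 7.60-fold, 9.45-fold and 11.4-fold higher, RAC2 was 2.64-fold, 2.46-fold and 2.25-fold higher, and NCF4 was 2.32-fold, 2.03-fold and 2.30-fold higher. The integrin ITGAM is not analysed here because no cluster named it alone.

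The median of the primary granule genes, which are made at the promyelocyte stage, fell in the later samples, with members moving both ways. The median of 13 measured members was -0.35 at 48 h, inside the random range, and then -2.15 at 72 h and -2.86 at 96 h, with 5, 7 and 7 members lower and 2, 2 and 3 higher at 48, 72 and 96 h. MPO, the myeloperoxidase gene, had a log2 difference of -0.41 at 48 h and was 4.45-fold and 7.26-fold lower at 72 and 96 h. ELANE, neutrophil elastase, was 2.74-fold, 4.99-fold and 7.55-fold lower. CTSG, cathepsin G, was 36.3-fold lower at 48 h and at least 167-fold lower at 72 and 96 h, where it lay at the floor. BPI, a bactericidal protein of the same granules, went the other way and was 105.9-fold, 43.9-fold and 23.6-fold higher. SERPINB1 (2.81, 2.69 and 2.68 on the log2 scale) and, at 96 h, lysozyme LYZ (1.38) were the other higher members, both named after their values were seen.

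Secondary and tertiary granule genes did not stand apart from random lists at any time, with medians of -0.80, 0.25 and 0.73 over 6 measured members, and another 10 of the list's genes lay under the level filter. Its median at 48 h was below the random range after quantile normalization (-0.86) and with arrays centred on their medians (-1.10). Within this list QPCT was 7.07-fold higher at 72 h and the log2 difference of ARG1 was 3.17 at 96 h. The gelatinase MMP9 was 4.59-fold lower at 48 h and had log2 differences of -0.078 and -0.39 at 72 and 96 h.

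Myeloid transcription factors moved in both directions, so the list as a whole did not shift (6, 7 and 7 of 18 members higher and 6, 7 and 6 lower). CEBPE, a regulator of granulocyte maturation, was 8.54-fold, 6.41-fold and 5.59-fold higher. SPI1 (PU.1) was 2.30-fold, 2.96-fold and 2.43-fold higher, and ID2 was 6.96-fold, 15.2-fold and 15.9-fold higher. MYC was 5.29-fold, 4.63-fold and 5.86-fold lower, and GATA2, a factor of progenitors and mast cells, was 5.96-fold, 15.2-fold and 10.9-fold lower. The list's median and mean had opposite signs at 48 h (-0.31 and 0.096) and at 96 h (-0.12 and 0.019), and the median turned to 0.17 at 48 h with reference centring and to 0.0093 at 96 h after quantile normalization. The blast and progenitor list had 5 measured members and stayed inside the random range, with medians of 0.15, 0.82 and 0.24 and means of -0.48, -0.79 and -0.72, and its median at 96 h turned to -0.014 after quantile normalization and to -0.064 with arrays centred on their medians. WT1 was 29.4-fold lower at 48 h and at least 117-fold lower afterwards, TERT, the telomerase catalytic subunit, was 2.13-fold, 2.40-fold and 2.55-fold lower, and the surface enzyme CD38 was 8.26-fold, 4.89-fold and 4.41-fold higher. CD33 is not analysed here, for the same reason as ITGAM.

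Interferon-stimulated genes rose at 48 h and rose further by 72 h. Of 24 measured members, 15, 21 and 22 were higher at 48, 72 and 96 h, and the list median was 1.60, 3.85 and 3.42. OAS3, an antiviral oligoadenylate synthetase at the floor in untreated cells, was at least 30.1-fold higher at 48 h and at least 105-fold higher at 96 h. OASL was at least 5.10-fold and then at least 38.2-fold and 34.2-fold higher, and IFI6 was 13.7-fold, 41.0-fold and 41.5-fold higher. HERC5 was 3.19-fold lower at 48 h and 2.94-fold higher at 96 h.

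Chemokines, cytokines and targets of NF-kB were raised from 48 h onward, with 15 of 20 measured members higher at each time and medians of 3.38, 3.32 and 3.29. CXCL10 rose from the floor by at least 65.2-fold, 110.3-fold and 51.1-fold, and the chemokine CCL22 was 22.3-fold, 99.2-fold and 96.3-fold higher. IL1RN, which encodes the interleukin 1 receptor antagonist, was 7.58-fold, 3.46-fold and 4.39-fold lower. The autophagy and lysosome list was shifted upward at the 3 times (0.64, 0.80 and 1.08; 4, 8 and 11 of 21 members higher, and 9, 13 and 13 after quantile normalization). Its transcription factor TFEB was 5.23-fold, 16.1-fold and 11.2-fold higher, and the cathepsins CTSS and CTSZ were 8.37-fold and 6.04-fold higher at 96 h.

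The apoptosis list shifted upward, with medians of 0.44, 0.57 and 0.78 over 18 members, of which 5, 5 and 9 were higher (12 at 72 h with reference centring). CFLAR, an inhibitor of death receptor signalling, was 2.57-fold, 2.73-fold and 2.94-fold higher. BCL2 was 26.7-fold lower at 48 h, at least 30.8-fold lower at 72 h and 28.5-fold lower at 96 h, and the death receptor TNFRSF10A was 2.74-fold, 4.14-fold and 3.27-fold lower. With the mean in place of the median the list no longer stood apart (0.21, 0.33 and 0.37). The coagulation and fibrinolysis list had medians of 0.35, 1.21 and 0.12 over 9 members and was shifted at 72 h, where its median was 0.40 without the level filter, and with the mean in place of the median it was also shifted at 48 h (0.77). In it, THBD (thrombomodulin) had log2 differences of 4.32, 4.52 and 3.39, PROS1 (protein S) was 4.92-fold, 5.14-fold and 5.23-fold higher, and the urokinase receptor PLAUR was 7.31-fold and 5.60-fold higher at 72 and 96 h. S100A10, a plasminogen-binding partner of annexin A2, was 2.54-fold lower at 96 h.

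**Figure D1:**
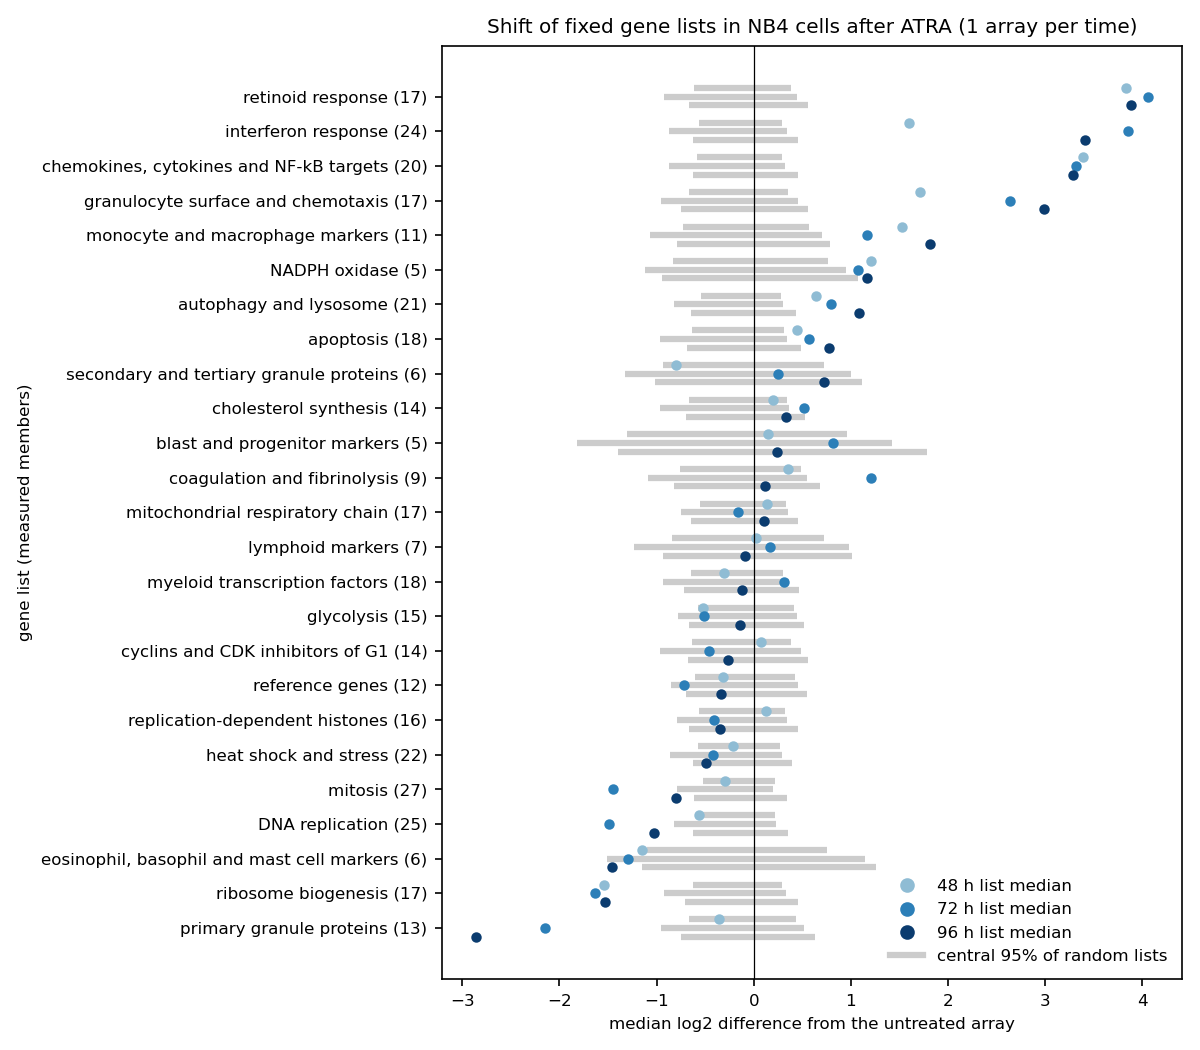
Median log2 difference from the untreated array (horizontal axis) for 25 gene lists with at least 5 measured members (vertical axis, number of measured members in brackets), with points for 48, 72 and 96 h of ATRA and 1 array per time, and grey bars for the central 95% of 10000 random lists matched on level. The retinoid response list lies at 3.83, 4.06 and 3.89, the primary granule list at -0.35, -2.15 and -2.86, and the ribosome biogenesis list at -1.54, -1.63 and -1.53.

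Ribosome biogenesis and DNA replication lists lay below random lists at 48, 72 and 96 h, and the mitosis list at 72 and 96 h. Ribosome biogenesis genes fell early and by a steady amount, with 15, 14 and 16 of 17 measured members lower and medians of -1.54, -1.63 and -1.53 (9 members lower at 72 h with reference centring). RRP1B was 5.70-fold, 7.50-fold and 5.38-fold lower, POLR1B, a subunit of RNA polymerase I, was 4.86-fold, 5.78-fold and 5.49-fold lower, and UTP20 was 3.72-fold, 8.68-fold and 4.08-fold lower. DNA replication genes had medians of -0.57, -1.48 and -1.03 over 25 members, outside the random range at each time and close to its edge at 48 h (percentile 2.37), with 6, 20 and 13 members lower. MCM10 was 2.55-fold, 3.71-fold and 3.33-fold lower, POLE 2.26-fold, 4.17-fold and 2.94-fold lower, and POLE2 2.07-fold, 4.47-fold and 2.85-fold lower.

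Mitosis genes had a median of -0.30 at 48 h, inside the random range, which turned to 0.0092 with reference centring, and fell to -1.44 at 72 h and -0.80 at 96 h, with 2, 22 and 10 of 27 members lower. PLK1, a mitotic kinase, was 2.13-fold, 3.54-fold and 3.36-fold lower. BIRC5 (survivin) was 2.37-fold, 4.53-fold and 3.20-fold lower, its 2 clusters moving alike, and the regulator FOXM1 was 3.84-fold and 2.39-fold lower at 72 and 96 h. The proliferation marker MKI67 had log2 differences of -0.27, -1.80 and -0.90. The scale of the arrays sets how many members pass: centred on reference genes, 7 and 3 mitosis genes and 10 and 6 replication genes were lower at 72 and 96 h, and 1 replication gene at 48 h, with medians of -0.83 and -0.50 for mitosis at 72 and 96 h and -0.26, -0.87 and -0.73 for replication. Genes of long genomic span read lower on the 72 h array than on the 96 h array (Spearman 0.299 across 8905 genes, which are not independent replicates).

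The G1 list, the replication-dependent histones and the lists of energy metabolism did not stand apart from random lists. G1 cyclins and CDK inhibitors had medians of 0.076, -0.46 and -0.26, which turned to 0.27 at 72 h and 0.26 at 96 h with reference centring, and were below the random range at these times under a stricter level filter (-1.54 and -0.90). Among them the CDK inhibitor CDKN1A was 5.88-fold, 4.89-fold and 5.21-fold higher, the cyclin CCND2 was 5.05-fold and 4.46-fold lower at 72 and 96 h, and CCNE1 was 6.24-fold and 2.07-fold lower. Histone genes, whose near-identical copies the probes could share, had medians of 0.12, -0.41 and -0.34, the one at 72 h turning to 0.20 with reference centring, with H4C4 2.07-fold and 2.25-fold lower at 72 and 96 h and log2 differences at 96 h of -0.74 for H3C7 and -0.51 for H4C3. None of the 17 measured members of the mitochondrial respiratory chain list passed the 2-fold rule on the deposited scale, while 4 did at 72 h with reference centring, and another 7 of its genes are not analysed here. The medians were 0.14, -0.16 and 0.10, and turned to 0.097 after quantile normalization and 0.46 with reference centring at 72 h, and to -0.0023 with arrays centred on their medians at 96 h. The log2 differences at 96 h were 0.97 for COXFA4, -0.71 for SDHA and at least 0.63 for COX7A2, which had 1 of its 2 clusters at the floor in untreated cells. Glycolysis had medians of -0.52, -0.52 and -0.14 and means of -0.021, 0.031 and 0.29, and its medians turned to 0.10 at 72 h and 0.16 at 96 h with reference centring. The myeloid hexokinase HK3 was 25.4-fold, 15.6-fold and 18.1-fold higher, ALDOC was 2.21-fold, 6.65-fold and 7.36-fold higher, and PFKP was 2.11-fold and 2.70-fold lower at 48 and 72 h. Cholesterol synthesis had medians of 0.20, 0.51 and 0.33 and was shifted upward at 72 h, though not with the mean in place of the median (0.41). MSMO1 was 2.35-fold and INSIG1 2.25-fold higher at 72 h, whereas LSS was 2.47-fold lower at 48 h and 2.07-fold lower at 72 h.

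Markers of monocytes and macrophages rose, with 6, 7 and 8 of 11 measured members higher and medians of 1.53, 1.17 and 1.81. The size of this shift depended on the members taken, with means of 2.75 and 2.87 at 72 and 96 h, medians of 2.14, 4.79 and 4.72 under the stricter level filter and 0.84, 1.04 and 1.07 without a filter. CD74, the class II invariant chain, was 9.42-fold, 125.5-fold and 140.6-fold higher, CX3CR1 was 8.17-fold, 41.1-fold and 58.4-fold higher, and CD86 was at least 3.53-fold, 30.4-fold and 60.0-fold higher. With reference centring 12 of the 12 members that then passed the level filter were higher at 72 h. Markers of eosinophils, basophils and mast cells had medians of -1.16, -1.29 and -1.46 over 6 members, below the random range at 48 and 96 h, and the median at 72 h turned to 0.60 with reference centring. PRG2, the eosinophil major basic protein, was 5.30-fold, 25.9-fold and 66.4-fold lower, HDC, which makes histamine, went from an intensity of 176.2 to the floor at all 3 times, and CLC, the Charcot-Leyden crystal protein, was 7.03-fold, 8.06-fold and 6.24-fold higher. That shift was lost at both times without the level filter (0 and -0.47) and with a floor of 64 (-0.68 and -0.46), and at 48 h also with reference centring (-0.45) and with the mean in place of the median (-0.87).

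Lymphoid markers stayed inside the random range (0.022, 0.16 and -0.091 over 7 members, with a mean of 0.20 and, with reference centring, a median of 0.53 at 96 h). CD79A was 6.60-fold, 5.42-fold and 4.0-fold higher, CD79B 5.88-fold, 4.34-fold and 4.76-fold lower, and CD3E 3.83-fold, 3.73-fold and 2.87-fold higher. Erythroid and megakaryocyte markers had 4 measured members each and were not ranked against random lists, with erythroid medians of -0.062, 0.21 and 0.15, the first turning to 0.015 after quantile normalization and 0.25 with reference centring, and megakaryocyte medians of 0.96, 0.59 and 1.38. Of the erythroid members, ERMAP was 2.11-fold higher at 96 h, while TFRC and KLF1 differed by -0.71 and 0.18. THBS1 (thrombospondin) rose from the floor by at least 25.6-fold, 42.6-fold and 69.8-fold, the integrin ITGB3 was 3.41-fold and 8.59-fold higher at 48 and 96 h, and ITGA2B had a log2 difference of -0.74 at 96 h.

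Heat shock and stress genes, which respond to handling, stayed inside the random range (-0.22, -0.42 and -0.49 over 22 members, the first 2 turning to 0.091 and 0.20 with reference centring). HMOX1 was 9.82-fold, 5.71-fold and 5.63-fold higher, XBP1 was 2.80-fold, 4.79-fold and 5.15-fold lower, and TRIB3 was 4.35-fold, 3.30-fold and 3.71-fold lower. The 12 measured reference genes had medians of -0.31, -0.72 and -0.34, also inside the range. POLR2A was 2.59-fold, 3.40-fold and 3.49-fold lower, GUSB was 2.06-fold and 2.23-fold higher at 48 and 96 h, and B2M was 2.03-fold higher at 96 h.

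ALOX5AP had reached 8.27 and CYP26A1 at least 7.07 on the log2 scale above untreated by 48 h, whereas the IgE receptor gene FCER2 and the lectin gene CD209 stood at 0.23 and 0.56 at 48 h and at 6.09 and 5.85 at 96 h. At 48 h, 897 genes were higher and 1229 lower than untreated. At 72 h the counts were 1274 and 2310, and at 96 h they were 1450 and 1384. Simulated unchanged arrays gave at most 351 genes in either direction. The share of higher genes among those past the rule was 42.2%, 35.6% and 51.2% at 48, 72 and 96 h, but 53.8%, 50.2% and 54.1% after quantile normalization, 40.4%, 39.8% and 42.6% with arrays centred on their medians and 71.2%, 78.4% and 74.3% with arrays centred on the reference genes. The median difference of all genes was -0.14, -0.27 and -0.13 as deposited, -0.0065, -0.039 and -0.10 after quantile normalization, -0.15, -0.20 and -0.24 with arrays centred on their medians and 0.20, 0.41 and 0.19 with reference centring, so the balance of directions depends on the scaling.

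The genes called at different times overlapped. Of the genes higher at 48 h, 757 were also higher at 72 h and 788 at 96 h, where independent lists would share 128 and 146 and simulated unchanged arrays shared 96.8 and 96.6. Of those lower at 48 h, 1081 were also lower at 72 h and 919 at 96 h, against 319 and 191 for independent lists and 74.5 and 75.2 in the simulation. Between 72 and 96 h, 1025 higher genes and 1261 lower genes were shared, against 207 and 359 for independent lists and 97.2 and 75.1 in the simulation. Across genes, which are not independent replicates, the log2 differences correlated at 0.879 (48 and 72 h), 0.865 (48 and 96 h) and 0.918 (72 and 96 h), against at most 0.502 in the simulation, with covariances of 1.29, 1.22 and 1.67 against 0.147. The simulated values hold the part that the shared untreated array gives at this level of noise.

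**Figure D2:**
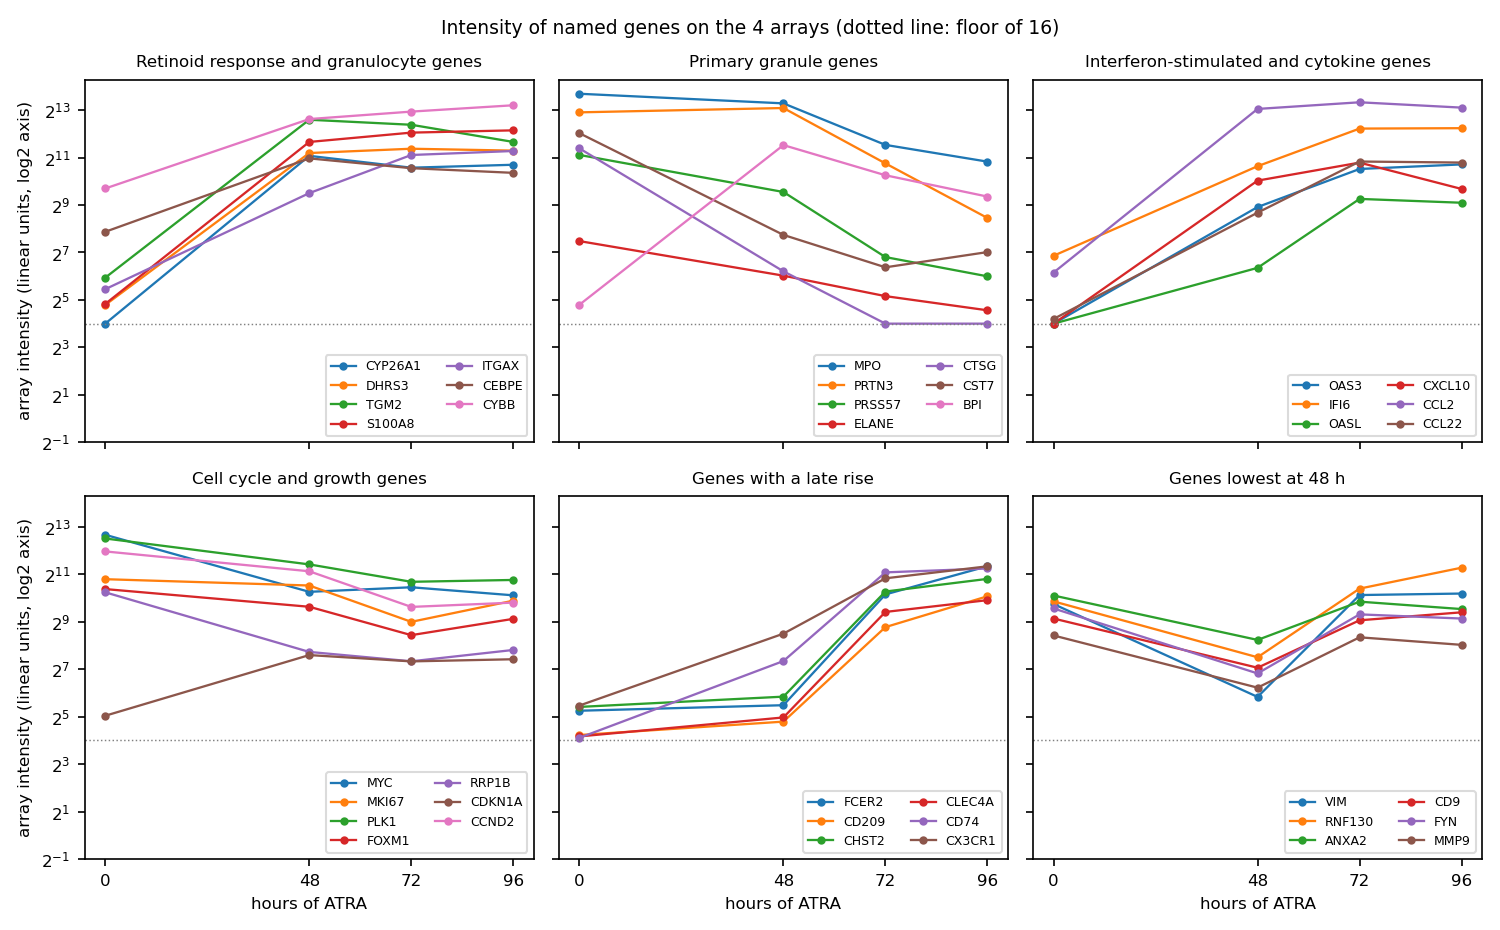
Intensity (vertical axis, linear array units on a log2 axis, values under 16 drawn at the dotted floor) against hours of ATRA (horizontal axis) for named genes in 6 panels, with 1 array per point and lines joining the points of a gene. MPO falls to 1816 at 96 h, MYC stands at 6493 untreated and 1108 at 96 h, and VIM dips to 57.0 at 48 h only.

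Within the treated cells, among genes with a 72 h value between the other 2 and values above the floor, the 5 largest rises from 48 to 96 h were those of FCER2, CD209, CHST2, CLEC4A and VIM. FCER2, the low-affinity IgE receptor (CD23), was 57.9-fold higher at 96 h than at 48 h, the lectins CD209 and CLEC4A were 38.9-fold and 30.8-fold higher, and the sulfotransferase CHST2 was 31.2-fold higher. These 4 genes differed from untreated by less than 1 on the log2 scale at 48 h (0.23, 0.56, 0.80 and 0.43). VIM, which encodes vimentin, rose 20.5-fold from 48 to 96 h, having been 15.1-fold lower than untreated at 48 h, and differed by 0.38 and 0.44 at 72 and 96 h. As many as 68 genes were lowest at 48 h in simulated unchanged arrays, against 36 observed, and the simulated counts lean high. Such a count does not judge the size of a single fall such as that of VIM, which was not tested. The largest falls were in PRTN3 (proteinase 3), 24.8-fold lower at 96 h than at 48 h, PRG2 (12.5-fold), the granule protease PRSS57 (11.7-fold), DEFA5 (9.02-fold) and the neuropeptide galanin, GAL (8.43-fold). DEFA5 has related defensin genes, and whether its probes also read them was not tested, so its identity is uncertain.

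From 48 to 72 h the interferon list rose by a further 1.60 on the log2 scale, the granulocyte surface list by 0.82 and the secondary and tertiary granule list by 1.34, while mitosis genes fell by 1.08, replication genes by 0.88 and primary granule genes by 1.27. From 72 to 96 h mitosis and replication genes came back up by 0.50 each, with 26 of 27 and 24 of 25 members higher, and by 0.18 and 0.19 with reference centring. Chemokine and cytokine genes moved down by 0.25 over the same step, as did the coagulation list by 0.38, which took its median back inside the random range. Monocyte markers rose by 0.57, coagulation genes by 0.55, chemokine and cytokine genes by 0.33, cholesterol genes by 0.33 and lysosome genes by 0.27 from 48 to 72 h. Over that step the log2 differences were -0.59 for G1 genes, -0.50 for histones, -0.50 for stress genes and -0.35 for reference genes. From 72 to 96 h they were -0.40 for primary granule genes, -0.20 for cholesterol genes, -0.38 for lymphoid markers and -0.086 for histones. With reference centring the sizes from 48 to 72 h moved to 0.99 for monocyte markers, 0.62 for chemokine and cytokine genes, 0.64 for cholesterol genes, 0.58 for lysosome genes, -0.57 for replication genes, -0.28 for G1 genes, -0.19 for histones, -0.19 for stress genes and -0.041 for reference genes. After quantile normalization the secondary granule step was 2.30. From 72 to 96 h, reference centring gave -0.54 for chemokine and cytokine genes, -0.66 for the coagulation list, -0.72 for primary granule genes, -0.51 for cholesterol genes, -0.69 for lymphoid markers and -0.40 for histones. On the deposited scale all of these steps lay outside the central 95% of random lists. Between 48 and 72 h, 380 genes were higher and 536 lower, and this order turned under the 3 other scalings (466 and 431 after quantile normalization, 450 and 405 with arrays centred on their medians, 771 and 206 with reference centring). Between 48 and 96 h the counts were 546 and 190. Between 72 and 96 h, 535 were higher and 203 lower, but this order also turned (289 and 371 after quantile normalization, 283 and 346 with arrays centred on their medians, 154 and 581 with reference centring). Simulated unchanged arrays gave means of 304 to 309 genes per direction, above the 203 and 190 lower genes observed. The counts of 380, 536, 535 and 546 lay above the highest simulated ones (348, 350, 347 and 354). The simulated noise is taken from the centred 96 against 72 h difference itself, so it cannot judge the counts between those times. The 2 latest arrays were the most alike (Pearson 0.931 on the log2 scale across genes).

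DOCK4, RNF130, HERC5 and OTULINL were at least 2-fold lower at 48 h and at least 2-fold higher at 96 h than untreated, with DOCK4 at -1.34 and 2.54 on the log2 scale. NECTIN1 went the other way, 2.06-fold higher at 48 h and 3.62-fold lower at 72 h. In all 12 genes crossed the 2-fold rule in both directions, 6 of them (DOCK4, RNF130, HERC5 and OTULINL included) lowest at 48 h. Simulated unchanged arrays gave up to 20 such genes, with a mean of 10.8. Their noise holds true change between 72 and 96 h as well, so they do not show whether noise alone gives as many. The differences between times were not tested.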

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

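Both tests of the late rise, the simulated count of genes that crossed in both directions and the counts of genes apart at 72 and 96 h under other scalings were chosen after the result was seen, and the tests of the mitosis and replication genes and of the genes lowest at 48 h were set before theirs.

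In all, 12 genes were at least 2-fold higher than untreated at some time and at least 2-fold lower at another, where simulated unchanged arrays gave up to 20, and the differences between times were not tested. DOCK4, RNF130, HERC5 and OTULINL were among the genes lowest at 48 h. DOCK4, a guanine nucleotide exchange factor, stood at -1.34 on the log2 scale at 48 h and 2.54 at 96 h. RNF130, a ubiquitin ligase, stood at -2.35 and 1.42, the interferon-induced ligase HERC5 at -1.67 and 1.56, and OTULINL at -1.56 and 1.34. The adhesion molecule NECTIN1 stood at 1.05 at 48 h and -1.85 at 72 h. Among transcript clusters left out of the comparisons because they name several genes or none, 3767 of 7579 passed the level filter, and 157 were higher and 248 lower than untreated at all 3 times.

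The C-type lectins CLEC10A and CLEC7A, the antigen-presenting molecules CD1C and CD1D and the invariant chain CD74 rose from 48 to 96 h, CLEC10A 61.0-fold, CD74 14.9-fold and CD1D 4.63-fold, although CD74 and CD1D already stood 9.42-fold and 8.01-fold above untreated at 48 h, all but CD74 named after their values were seen. The labels name only NB4 cells, an established line, as the source of the RNA. Monocytes or dendritic cells mixed into the later cultures could bring class II genes and CD14 along. The median rise of HLA-DRA, HLA-DPA1, HLA-DPB1, CD14 and VCAN was 0.071 against 3.90 for CD74. This median cannot decide on such cells as the source. The markers in it read low on each array, at most 205.3 (HLA-DPB1 at 72 h). Whether their probes would follow such cells was not tested. The levels at 96 h (103.6 for HLA-DRA, 126.4 for HLA-DPA1 and 85.5 for CD14, against 2427 for CD74) come from different probes. They do not measure the share of such cells. HLA-DRA itself rose from the floor by at least 2.69, which the median does not show. Of 11 members of the fixed monocyte list, 9 were higher at 96 h than at 48 h, but the list's median step of 0.27 lay inside the random range. CD86 rose by 4.09, CX3CR1 by 2.84 and CSF1R, named after its values were seen, from an intensity of 174.2 to 791. NB4 cells that express these genes would give the same values, so the rises do not show whether other cells were present. At 48 h, 2344 clusters lay at or under the floor, fewer than the 2769 at 72 h and 2393 at 96 h. An array with a raised low end would also give fewer, so this count cannot decide on a poor reading of low-level genes at 48 h, which stays open. A change in the cells with time under ATRA stays open as a hypothesis, as do other differences between single cultures.

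Mitosis and DNA replication genes were lower at 72 h than at 96 h, with 50 of 52 members higher at 96 h. After quantile normalization the median difference was 0.31, and with reference centring 0.18 for mitosis and 0.19 for replication genes. These remaining sizes argue against a lower scale of the 72 h array as the whole cause. The 0.31 lay at the 100th percentile of random lists, which adds little, since a shift of scale moves a list and its random lists alike. Genes of long genomic span did read lower at 72 h, with a median difference from 72 to 96 h of 0.41 for the longest genes and -0.092 for the shortest. Among random lists matched on span the median of 0.50 again lay at the 100th percentile, so span alone does not account for it. Growth state of the single 72 h culture and the time under ATRA cannot be separated with 1 array per time and stay open, untested.

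The cytoskeletal gene VIM, the kinase FYN, CD9 and ANXA2 were at least 2-fold lower at 48 h than on each other array, and FYN, CD9 and ANXA2 were named after their values were seen. Array noise was not excluded as the source of such a set. The pattern was shown by 36 genes against a highest simulated count of 68, and the simulated counts lean high. The sizes of single genes such as VIM were not tested. After quantile normalization the count was 33, which decides nothing about a lower scale of the 48 h array, since 36 already lay under 68. At 72 h 149 genes were lowest, against at most 64 simulated (81 after quantile normalization and 23 with reference centring). The 30 genes highest at 72 h did not exceed the simulated 51 (55 and 140 under these scalings), and 86 were highest at 96 h against at most 48 (55 and 44). These sets depend on the scale. The simulated noise is the 96 against 72 h difference with its median of 0.21 taken out, which the observed counts keep. The simulation therefore cannot judge the counts at 72 and 96 h. No biological explanation was tested.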

How the results depend on the processing

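Reference centring, no floor and a floor of 64 were chosen after the data were seen, and the other alternatives were fixed before. No paired analysis was possible because each group had 1 array. Under the alternatives, 89 counts of genes stayed within 1.5 times the reported count and 57 did not. Of the list shifts, 722 kept their side of the random range, 6 passed it and 10 no longer did, and no called list or gene past the size rule changed sign. Values of named genes moved by more than the spread of the 96 against 72 h difference (0.482) in 435 of the comparisons and by less in 2445, with 0 moved by quantile normalization or median centring, 138 by reference centring, 162 by a floor of 64, 103 by the pseudocount and 32 without a floor. Signal over background limits the low genes, since folds against the floor are bounds. Folds from untreated intensities just above it, such as those of CD74 (17.3), CCL22 (18.4) and BPI (27.8), are uncertain in size.

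A size rule of 1.5-fold, looser by construction, gave 1773 higher and 2642 lower genes at 48 h, 2088 and 3512 at 72 h, 2350 and 2839 at 96 h and 1234 and 2073 at all 3 times. It gave 952 and 1658 from 48 to 72 h, 1926 and 637 from 72 to 96 h and 1353 and 697 from 48 to 96 h. A rule of 3-fold, stricter by construction, gave 441 and 394, 686 and 854, 793 and 438, and 393 and 274 in the same order, then 174 and 87, 70 and 27, and 234 and 44. The filter at the 70th percentile, with fewer genes tested, gave 821 higher at 72 h, 954 higher at 96 h, 241 higher and 302 lower from 48 to 72 h, 218 and 49 from 72 to 96 h, and 317 and 92 from 48 to 96 h. Without a filter, with more genes tested, 643 were higher and 866 lower from 48 to 72 h, 905 and 575 from 72 to 96 h, and 465 lower from 48 to 96 h. Reference centring, which shifts each array by construction, gave 1518 higher and 614 lower at 48 h, 2784 and 765 at 72 h, 724 lower at 96 h, 1145 and 387 at all 3 times, 771 and 206 from 48 to 72 h and 154 and 581 from 72 to 96 h. From 72 to 96 h, quantile normalization gave 289 and 371, median centring 283 and 346, and the pseudocount 353 higher, and for the pseudocount the cause was not tested. Leaving out 48, 72 or 96 h gave 1025, 788 and 757 higher and 1261, 919 and 1081 lower genes at both remaining times.

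Among lists, eosinophil, basophil and mast cell markers lost their shift at 48 h with reference centring (-0.45), a floor of 64 (-0.68), the mean (-0.87) and no filter (0.0), and at 96 h with a floor of 64 (-0.46) and no filter (-0.47), and gained one at 72 h without a floor (-1.52). Apoptosis lost its shift with the mean (0.21, 0.33 and 0.37), and so did cholesterol synthesis at 72 h (0.41), while coagulation gained one at 48 h (0.77). G1 cyclins and CDK inhibitors gained a shift under the 70th percentile filter at 72 h (-1.54) and 96 h (-0.90), and secondary and tertiary granule proteins at 48 h with median centring (-1.10) and quantile normalization (-0.86). The cause of these list changes was not tested. Centring shifts a list and its random lists alike, so it tests a list's place among them only through the level filter. Medians of other shifted lists that moved by over 1.5 times were those of the retinoid list at 48 h without a filter (2.10), primary granule genes under the stricter filter (-1.20 at 72 h and -1.37 at 96 h), with the mean (-1.33 and -1.63) and with a floor of 64 (-1.48 at 96 h), and, with reference centring, the NADPH oxidase (1.69), lysosome (1.41), apoptosis (1.19), cholesterol (1.13) and ribosome biogenesis (-1.01) lists at 72 h. Apoptosis moved to 0.75 at 48 h with reference centring and to 0.43 at 96 h with median centring, cholesterol synthesis to 0.79 at 72 h after quantile normalization, and eosinophil markers to -0.68 at 96 h with reference centring.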

Other observations

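The families of translation and protein turnover were tested after the data were seen, and the single genes here were named after their values were seen and stand for no group.

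PTGES, a prostaglandin E synthase at the floor in untreated cells, was at least 77.7-fold, 80.1-fold and 55.2-fold higher at 48, 72 and 96 h. PTGS1 (cyclooxygenase 1) was 9.17-fold, 9.0-fold and 6.99-fold higher, ALOX5 2.91-fold and 3.17-fold higher at 72 and 96 h, and the prostaglandin receptors PTGER2 and PTGER4 17.6-fold and 7.26-fold higher at 96 h. The arginine deiminase PADI2 was at least 143.8-fold and PADI4, which is found in neutrophils, 30.0-fold higher at 48 h. G0S2, a lipolysis inhibitor, was at least 251.5-fold, 408.6-fold and 162.2-fold higher. The antigen processing genes PSMB8 and PSMB10 were 3.91-fold and 3.10-fold higher at 48 h and WARS1 was 3.99-fold higher at 96 h, and PARP9 and PARP14 were 13.2-fold and 36.4-fold higher at 96 h. HLA-E and HLA-F were 4.42-fold and 5.16-fold higher at 96 h, with some uncertainty from related HLA genes. CYTL1, at an intensity of 6983 in untreated cells, lay at the floor at all 3 times, and ZBTB16 (PLZF) was 20.6-fold lower at 48 h and at least 31.8-fold lower afterwards.

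The amino acid transporters SLC7A5, SLC7A1 and SLC38A5 were 15.7-fold, 5.39-fold and 4.46-fold lower at 48 h. The serine synthesis genes PHGDH and PSAT1 were 8.59-fold and 7.97-fold lower at 72 h, and the pyrimidine and purine synthesis genes CAD and PAICS 4.87-fold and 3.73-fold lower. The DNA methyltransferase DNMT3B was 11.5-fold lower and TET1 16.6-fold lower at 72 h, against 5.76-fold and 3.06-fold at 96 h. Their intensities at 72 h (33.2 and 17.3) lay under the lower quartile of that array (37.3), so the sizes at 72 h are uncertain.

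Cytosolic aminoacyl-tRNA synthetases lay below random lists of the same level, with medians of -0.87, -1.05 and -0.93 over 18 genes and a percentile of 0.03 at 96 h. Of these genes 5, 10 and 8 were lower at 48, 72 and 96 h, and 1 was higher at each time. The medians stayed negative under each scaling (-0.56, -0.43 and -0.63 with reference centring). Mitochondrial ribosomal proteins had medians of -0.54, -0.51 and -0.61 over 64 genes, with percentiles of 0.1, 13.3 and 0.11, and the median at 72 h turned to 0.11 with reference centring. Proteasome subunits stayed inside the random range, with medians of -0.41, -0.32 and -0.45 over 28 genes and a percentile of 9.43 at 96 h, and the median at 72 h turned to 0.29 with reference centring.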
